A study of Mus musculus with 12 samples.

How the data were processed

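Gene expression in the liver of adult female mice was measured on 12 one-colour Affymetrix 3' expression arrays, 1 array per sample. Per the labels' protocols, total RNA was isolated with Trizol, cleaned on columns with DNase treatment, and amplified and labelled with a 3' IVT kit. The submitters' processing notes name Affymetrix Expression Console and MAS5, with versions not given in the sources used here. The authors deposited 1 linear intensity (MAS5 signal) per probe set and array, as the values show. On each array the mean of the 45101 deposited intensities, without the lowest and highest 2%, was 500, so the arrays had been scaled to a common level before deposit. MAS5 combines the probes of a probe set into 1 value and works on each array separately. Signals near background therefore scatter widely on a log scale, and fold differences from them are uncertain. Detection flags and scanner files were not used here. No slide or scan batch was used here.

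Samples were placed in 4 groups of 3 by the genotype, diet and replicate number in their labels. The labels do not say that replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values (0 identical array pairs). Pearson correlations of the log2 values ranged from 0.945 to 0.976 within groups and from 0.930 to 0.975 between groups. Array medians of the signal lay between 75.6 and 114, and the highest belonged to WT normal replicate 3. The number of arrays limits the precision. The median standard error of a log2 difference was 0.202 between 2 groups and 0.285 for the interaction.

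Probe sets were named through the platform annotation supplied with the table, with symbols updated through Entrez identifiers in a RefSeq gene table. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Only probe sets with 1 symbol entered the gene table. For each of the 18194 genes the probe set with the highest mean signal over the 12 arrays was taken. Genes were kept when their signal exceeded the array's median on at least 3 of the 12 arrays, which left 12264 genes, 7359 of them with several probe sets. Values were log2(signal + 16), so differences of weakly expressed genes are understated. Transcripts of near-identical genes, as in the Cyp2b, Cyp3a, Slc22a, Sult and Nat8 families, can bind each other's probes, and their single values are uncertain in that respect. In tests of this, every list member whose symbol begins with Cyp, Sult, Slc22a, Mup, Ugt, Nat8 or Gst was counted as inside such a family, which is a broad definition. Genes are identified by symbol, and no genome coordinates are given, since the sources used here name no genome build.

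Differences were tested in R 4.3.3 with limma 3.58.1. A single linear model with a mean for each group was fitted to all 12 arrays, so that the groups shared an estimate of the spread with 8 residual degrees of freedom. Variances were moderated with an intensity trend (5.85 prior degrees of freedom). The 4 comparisons between 2 groups were diet within each genotype and genotype within each diet. The interaction was the diet difference in the knockout minus that in wild type. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 12264 genes, and a gene was called at an adjusted p under 0.05. Errors of signals are SD over 3 samples, and errors of log2 differences are standard errors from the model.

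There were 27 gene lists fixed before the data were examined, together with the groups, tests, alternatives planned and the rule for naming genes. They covered fatty acid synthesis, cholesterol synthesis, PPAR alpha targets and fatty acid oxidation, lipid droplets and triglyceride storage, lipoproteins, bile acids, glucose metabolism, female-biased and male-biased liver genes, hormone receptors and growth hormone signalling, xenobiotic metabolism, acute phase, interferon response, endoplasmic reticulum stress, the circadian clock and the cell cycle. Further lists held markers of pericentral and periportal hepatocytes, stellate cells, macrophages, sinusoidal endothelium, lymphocytes, neutrophils and pancreatic acinar cells. The 3 lists of cholangiocyte, red blood cell and adipocyte markers had fewer than the 4 measured members required and were not tested, which left 24 lists. Lists were tested with camera in limma (competitive, two-sided, preset correlation 0.01, adjusted over the 24 lists of a comparison), and again with a correlation estimated for each list. Of the 120 list tests, 38 passed with the preset correlation and 6 with the estimated correlation. Those 6 were the male-biased and female-biased lists for genotype on both diets, the PPAR alpha list for genotype on normal diet and the female-biased list for diet in the knockout. The median, mean and test direction of a list differed in sign in 19 of the 120 tests, 0 of which passed with the preset correlation. Acot3 and Vldlr were also on the female-biased list, Cyp7b1 and Slco1a1 on both the male-biased and the bile acid list, Cyp2b10 on both the female-biased and the xenobiotic list, and Cyp1a2 on both the xenobiotic and the pericentral list.

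The genes named are, for each comparison between 2 groups, the 8 largest rises and 8 largest falls among called genes whose 3 arrays of a group all lay above the 3 of the other, and up to 4 members of each list by smallest p, of which mainly the called ones are described. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p were taken instead. For the interaction the rule took 5 genes in each direction. Esr1 was always included, and uncharacterised clones were counted without being named. Complete separation of 3 against 3 arrays arises by chance for 10% of genes.

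The pipeline was tested on simulated data with 12264 genes, of which 200 had been changed, in 5 simulations. Noise was drawn from a normal distribution, separately for each gene and array, with the moderated spread of the fit. Correlation between genes and arrays that deviate as a whole were not simulated, so the shares below hold for such noise only. For diet in wild type 26.6% of 1.5-fold, 61.5% of 2-fold and 93.3% of 4-fold changes were recovered. For the interaction the shares were 4.18%, 33.7% and 81.8%. A mean of 7 unchanged genes per simulation were called falsely among 115 to 135 calls for diet in wild type, and 0 in a comparison without simulated changes.

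Alternatives planned before the data were examined were pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, quantile normalization, median centring, the mean of all probe sets of a gene, no intensity trend, only the groups compared in the fit, array quality weights, the replicate number as a block, an estimated list correlation, and each array left out in turn. Pancreatic transcripts were found on 4 arrays and muscle transcripts on some arrays, with αERKO normal replicate 1 high in both. Therefore 3 alternatives were added after seeing the data: the pancreatic score as a covariate, the pancreatic and muscle scores as covariates, and the data without the 4 arrays with pancreatic transcripts. The scores are mean log2 values of 7 acinar genes and of 10 muscle genes, the latter chosen after seeing the data.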

Results

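Liver transcripts were measured in adult female mice of a B6.129 background that were wild type (WT) or αERKO, which are homozygous for a disrupted Esr1, the gene of estrogen receptor alpha. Mice of each genotype were fed NIH-31 chow, called normal diet here, or a diet with 60 kcal% fat for 2 weeks. Whether these 2 diets matched in other ingredients was not examined. Diet differences below are therefore between the diets as a whole and cannot be put down to fat alone. Each of the 4 groups held 3 samples with 1 array each. The comparisons ask how the liver differs without the receptor on each diet, how it responds to a fat-rich diet in each genotype, and whether that response depends on the receptor.

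Some arrays carried transcripts of other tissues. The mean log2 signal of 7 pancreatic acinar genes, which encode digestive enzymes, was 14.0 in WT normal replicate 2, 13.7 in αERKO normal replicate 1, 12.7 in WT high-fat replicate 3 and 10.2 in WT high-fat replicate 2, and lay between 5.95 and 6.87 on the other 8 arrays. Prss2, a trypsinogen, had signals of 24900, 17500, 8440 and 1350 on these 4 arrays, in the same order. The mean log2 signal of 10 skeletal muscle genes was 11.002 in αERKO normal replicate 1, 9.52 in αERKO high-fat replicate 2 and 7.36 in αERKO normal replicate 2. It was 6.796 in WT normal replicate 3 and lay between 5.48 and 6.06 on the remaining arrays. WT normal replicate 3 had the highest array median and, at 6.87, the highest acinar score of those 8 arrays, so its muscle score need not mean muscle transcripts.

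**Figure D1:**
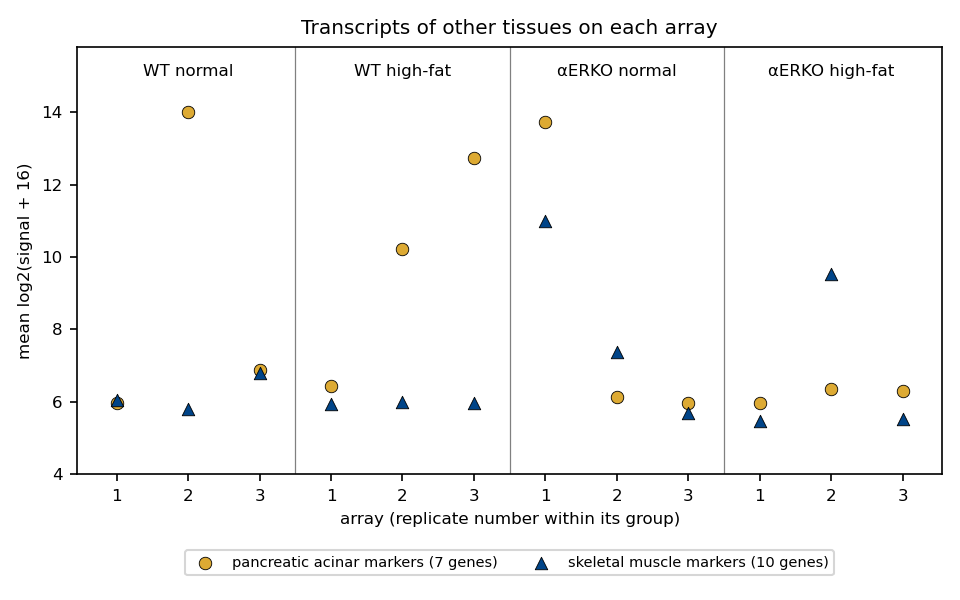
Mean log2(signal + 16) of 7 pancreatic acinar genes (circles) and 10 skeletal muscle genes (triangles) on each of the 12 arrays, by group and replicate number. The acinar score exceeded 10 on 4 arrays, in WT normal, WT high-fat and αERKO normal, and the muscle score was highest on αERKO normal replicate 1 at 11.002.

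By the 2 brighter of its 3 probe sets, Esr1 was lower in every knockout sample than in every wild type sample. The brightest gave signals of 2437.9, 3929.6 and 1963.2 in WT normal replicates 1 to 3 (mean 2780 ± 1030 SD, n = 3) and 3212.2, 3676.0 and 3140.2 in WT high-fat (3340 ± 291). The knockout values were 681.3, 586.1 and 601.0 on normal diet (623 ± 51.2) and 885.3, 663.4 and 857.7 on high-fat diet (802 ± 121). The log2 difference between genotypes was -2.07 ± 0.20 (SE) on normal diet (adjusted p = 5.75e-05) and -2.05 ± 0.20 on high-fat diet (adjusted p = 8.55e-05). A second probe set fell from 786 ± 269 to 146 ± 50.7 on normal diet. The third was dim and did not separate the genotypes in every sample, at 32.2 ± 26.3 in WT normal, where replicate 2 gave 7.6, and 17.1 ± 6.78 in αERKO high-fat. Signal remained in the knockout, and where these 3' probe sets lie relative to the disrupted part of the gene was not examined, so the values check the labels no further than this. Diet moved Esr1 by 0.32 ± 0.20 in wild type (adjusted p = 0.724) and by 0.35 ± 0.20 in the knockout (adjusted p = 0.606).

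On normal diet the knockout liver had much higher signals of genes typical of male liver and lower signals of genes typical of female liver. Cyp4a12a, a male-specific fatty acid hydroxylase, was higher by 7.42 ± 0.53 on the log2 scale (adjusted p = 2.95e-06), and Cyp2d9, a male-biased steroid hydroxylase, by 3.76 ± 0.15 (adjusted p = 3.32e-09). The sulfotransferases Sult2a2 and Sult3a1 differed by -8.84 ± 0.79 and -7.24 ± 0.47. Cyp2b13, a female-specific cytochrome P450, differed by -7.36 ± 0.29 (adjusted p = 3.32e-09), from a log2 signal of 13.82 ± 0.14 to 6.46 ± 0.04 (SD, n = 3). For Cyp4a12a, Sult2a2, Sult3a1 and Cyp2b13 the lower group lay below the array median on all 3 arrays, so the sizes of these differences are imprecise. In all, 150 genes were called, 72 higher and 78 lower in the knockout, and 76 of them differed at least 2-fold.

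Of 17 measured male-biased genes, 11 were higher and 0 lower (12 higher when adjusted over the list alone), with a median log2 difference of 1.142 and an adjusted p of 2.76e-30, or adjusted p = 0.000916 with an estimated correlation. Next to Cyp4a12a and Cyp2d9 these included the organic anion transporter Slco1a1 (5.75 ± 0.82), the fatty acid elongase Elovl3 (3.03 ± 0.20), Susd4 (3.09 ± 0.36) and Nat8 (2.85 ± 0.27). Of 23 measured female-biased genes, 13 were lower and 0 higher (16 lower when adjusted over the list alone), with a median of -1.11 and an adjusted p of 3.85e-28, or adjusted p = 7.38e-05 with an estimated correlation. Among these were Cyp3a16 (-5.60 ± 0.64), the peroxisomal hydroxyacid oxidase Hao2 (-3.998 ± 0.30), the transporters Slc22a26 (-3.21 ± 0.21) and Slc22a27 (-3.01 ± 0.22), and the transcription factor Cux2 (-3.08 ± 0.47), for which 1 of 3 probe sets went the other way.

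The PPAR alpha targets and fatty acid oxidation genes were shifted down. Of 27 measured, 4 were lower and 0 higher (17 lower and 1 higher when adjusted over the list alone), with a median of -0.267 and an adjusted p of 1.44e-11, or adjusted p = 0.0372 with an estimated correlation. The called members were the acyl-CoA thioesterases Acot2 (-1.01 ± 0.17), Acot3 (-1.38 ± 0.27) and Acot4 (-0.99 ± 0.22) and the peroxisomal oxidation enzyme Ehhadh (-0.49 ± 0.09). This list was tested against all other genes, not against genes of similar signal. Alb, a bright liver gene outside it, was lower too, with log2 signals of 16.068, 16.072 and 16.318 in WT normal and 15.711, 15.713 and 15.545 in αERKO normal. Whether the shift is particular to the pathway was not tested. Of 22 lipid droplet genes, 2 were higher, Cidea (2.87 ± 0.52), which promotes droplet growth, and Fitm1 (1.45 ± 0.20), which acts in droplet formation, and the list as a whole did not pass (adjusted p = 0.674). The lipoprotein list (20 measured, median -0.199) held 2 lower genes, the receptor Vldlr (-1.11 ± 0.16) and Apoa2 (-0.39 ± 0.09), and 11 when adjusted over the list alone. It passed at an adjusted p of 0.0393, but adjusted p = 0.443 with an estimated correlation. The endoplasmic reticulum stress list (21 measured, 0 called, 0 when adjusted over the list alone, median 0.138) had an adjusted p of 0.00717, and adjusted p = 0.279 with an estimated correlation. The macrophage markers (15 measured, 0 called, 1 lower when adjusted over the list alone, median -0.337) had an adjusted p of 0.00200, and adjusted p = 0.629 with an estimated correlation. Other called genes were Ccnd1, which encodes cyclin D1 of the G1 phase (-2.27 ± 0.23, adjusted p = 8.59e-05), the ferritin receptor Scara5 (4.33 ± 0.73), the glutathione transferase Gsta2 (1.19 ± 0.26), Aldh1a7 (0.58 ± 0.13) and the periportal cytochrome P450 Cyp2f2 (0.62 ± 0.12). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, was higher by 1.75 ± 0.21, although 1 of its 3 probe sets went the other way and the mean of its probe sets was not called (adjusted p = 0.155).

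For 7 of the 29 called genes named for this comparison the lower group lay below the array median on every array, so that these folds are imprecise. The count fell to 95 without WT normal replicate 3, to 97 without αERKO normal replicate 1, to 85 without αERKO normal replicate 2, to 83 without the intensity trend, to 71 with only the groups compared in the fit, and to 80 without the 4 arrays with pancreatic transcripts, and with median centring 60.1% of calls were higher in the knockout against 48.0% with the deposited scaling.

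On high-fat diet the same contrast between genotypes was present for sex-biased genes, and more genes of lipid droplets were called. Cyp4a12a was higher in the knockout by 4.97 ± 0.53 (adjusted p = 0.000124) and Cyp2d9 by 3.28 ± 0.15 (adjusted p = 3.54e-08). Cyp3a16 differed by -6.46 ± 0.64, Sult2a2 by -6.77 ± 0.79, Sult3a1 by -5.84 ± 0.47 and Cyp2b13 by -5.75 ± 0.29. Cidea was higher by 4.77 ± 0.52 (adjusted p = 0.000151), from a log2 signal of 4.90 ± 0.70 to 9.67 ± 1.07 (SD, n = 3), and since its WT signal lay below the array median on all 3 arrays the size of this difference is imprecise. The same held for 6 of the 37 called genes named for this comparison. In all, 243 genes were called, 135 higher and 108 lower, 88 of them at least 2-fold.

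Of the 17 male-biased genes, 8 were higher and 0 lower (14 higher when adjusted over the list alone), with a median of 1.091 and an adjusted p of 2.42e-19, or adjusted p = 0.00438 with an estimated correlation. They included Elovl3 (3.26 ± 0.20) and Nat8 (3.31 ± 0.27), and the related Nat8f5 was higher by 3.74 ± 0.18. Of the 23 female-biased genes, 13 were lower and 0 higher (15 lower when adjusted over the list alone), with a median of -1.06 and an adjusted p of 4.31e-19, or adjusted p = 0.000329 with an estimated correlation, and they included Cux2 (-3.34 ± 0.47), Slc22a26 (-2.73 ± 0.21) and Cyp3a44 (-2.41 ± 0.29).

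**Figure D2:**
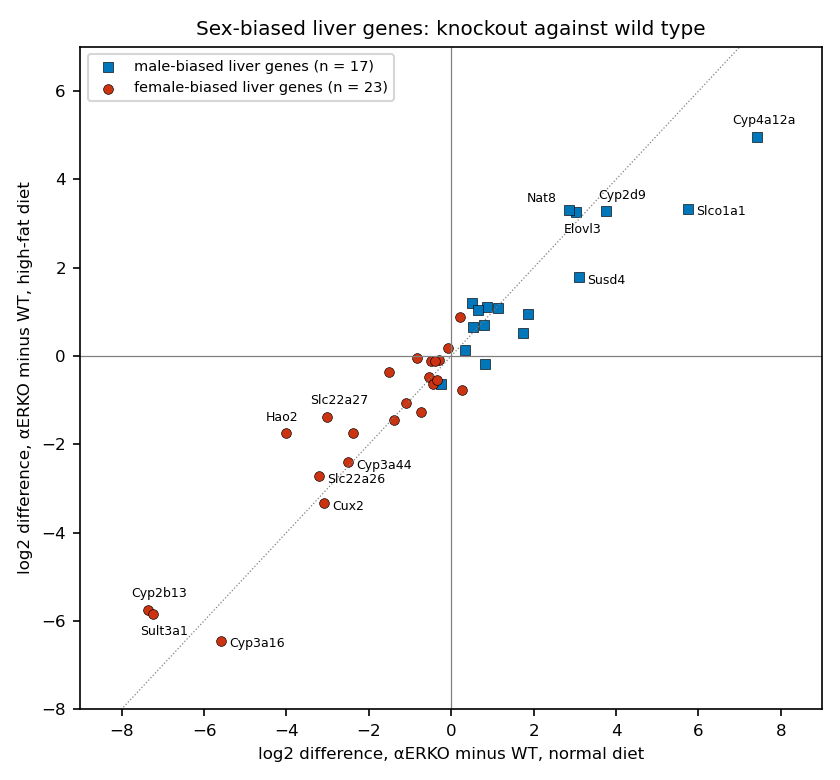
Log2 difference between αERKO and WT (n = 3 arrays per group) on normal diet (horizontal axis) and on high-fat diet (vertical axis) for 17 male-biased genes (squares) and 23 female-biased genes (circles), with equal differences along the dotted line. The median difference of the male-biased genes was 1.142 on normal diet and 1.091 on high-fat diet, and that of the female-biased genes -1.11 and -1.06.

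Of 22 lipid droplet genes, 4 were higher and 0 lower (5 higher when adjusted over the list alone), namely Cidea, Cidec (2.60 ± 0.47), Fitm1 (2.20 ± 0.20) and Mogat1 (2.15 ± 0.32), a monoacylglycerol acyltransferase. The list had a median of 0.161 and an adjusted p of 0.000666, but adjusted p = 0.355 with an estimated correlation. Scd1, the stearoyl-CoA desaturase, was higher by 1.13 ± 0.24. Of 21 endoplasmic reticulum stress genes, 3 were higher (5 when adjusted over the list alone), Creld2 (1.35 ± 0.18), Manf (1.32 ± 0.22) and the chaperone Calr (0.46 ± 0.11). That list had a median of 0.346 and an adjusted p of 1.02e-05, but adjusted p = 0.0684 with an estimated correlation. Of 27 PPAR alpha genes, 3 were lower (8 when adjusted over the list alone), Ehhadh (-0.74 ± 0.09), Acot3 (-1.44 ± 0.27) and Acot1 (-1.21 ± 0.28), with a list median of -0.205 and an adjusted p of 4.04e-07, but adjusted p = 0.102 with an estimated correlation. Of 20 hormone and growth hormone signalling genes, 2 were lower (3 when adjusted over the list alone), Esr1 itself and Igfbp2, an insulin-like growth factor binding protein (-1.64 ± 0.17, adjusted p = 0.000117). That list had an adjusted p of 0.0232, but adjusted p = 0.355 with an estimated correlation. Of 20 xenobiotic genes, 3 were higher and 1 lower (6 and 3 when adjusted over the list alone), Aldh1a7 (1.01 ± 0.13), Gsta2 (1.504 ± 0.26), Aldh1a1 (0.41 ± 0.08) and Cyp2c37 (-0.45 ± 0.10), and the list had an adjusted p of 0.00640, but adjusted p = 0.559 with an estimated correlation.

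Cholesterol synthesis genes (20 measured, median 0.369) and acute phase genes (22 measured, median 0.250) had 0 called members each, and 0 when adjusted over the list alone. Their adjusted p was 0.00160 and 0.00640, but adjusted p = 0.603 with an estimated correlation for both. Each lost its call when 1 array was left out, for example cholesterol synthesis without αERKO high-fat replicate 3 (median 0.084, adjusted p = 0.451) and acute phase without αERKO high-fat replicate 1 (median 0.154, adjusted p = 0.246). The macrophage markers (15 measured, 0 called, 1 lower when adjusted over the list alone, median -0.314) had an adjusted p of 0.00640, and adjusted p = 0.603 with an estimated correlation. The interferon list (19 measured, median -0.340) held 1 lower gene, Gbp3 (-1.004 ± 0.24), with 1 higher and 1 lower when adjusted over the list alone, and its adjusted p was 0.0233, but adjusted p = 0.597 with an estimated correlation. The 7 pancreatic acinar genes had 0 called members and 0 when adjusted over the list alone, with a median of -3.953, an adjusted p of 0.0232, and adjusted p = 0.603 with an estimated correlation. High acinar scores occurred in 2 of the 3 WT high-fat arrays and in no αERKO high-fat array. Other called genes were Ccnd1 (-2.42 ± 0.23), Vldlr (-1.06 ± 0.16), Baat, which conjugates bile acids (0.54 ± 0.11), the clock repressor Cry1 (0.96 ± 0.22), Cyp2f2 (0.67 ± 0.12), Omd (2.82 ± 0.31) and the noncoding Snhg11 (2.66 ± 0.36).

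The count fell to 122 without WT high-fat replicate 1, to 132 without WT high-fat replicate 2, to 122 without αERKO high-fat replicate 1, to 108 without αERKO high-fat replicate 2, to 116 without the intensity trend, to 108 with the pancreatic and muscle scores as covariates, and to 60 without the 4 arrays with pancreatic transcripts, and it rose to 944 with array quality weights. With median centring 71.1% of calls were higher in the knockout against 55.6% with the deposited scaling.

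Genotype differences were shared between the diets. Of the called genes, 82 were called on both diets in the same direction, 44 higher and 38 lower in the knockout, against 0.793 and 0.687 for independent lists, and 0 were called in opposite directions. Among the 311 genes called on either diet, 286 had the same sign on both. Across the 12264 genes, which are not independent replicates, the log2 differences on the 2 diets had a Pearson correlation of 0.43 and a Spearman correlation of 0.32. The 2 comparisons share no arrays, but they share the variance estimate of each gene. Their calls are therefore not independent, and the numbers for independent lists are only a rough guide.

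In wild type liver 2 weeks of high-fat diet changed few genes past the threshold. Ces2a, a carboxylesterase, fell by 1.17 ± 0.12 on the log2 scale (adjusted p = 0.00263), and Pltp, the phospholipid transfer protein, fell by 1.44 ± 0.18 (adjusted p = 0.00742). Csad, an enzyme of taurine synthesis (-1.93 ± 0.26), the desaturase Scd1 (-1.501 ± 0.24), the glutathione transferase Gstm1 (-0.72 ± 0.12), the acyl-CoA binding protein Dbi (-0.67 ± 0.09) and the retinol dehydrogenase Rdh16 (-0.66 ± 0.10) fell as well. Gamt, an enzyme of creatine synthesis, rose by 0.90 ± 0.14 (adjusted p = 0.0260) and Tlcd2 by 0.82 ± 0.14 (adjusted p = 0.0472). These 9 genes, 2 up and 7 down, were all that were called, and for 0 of them did the lower group lie below the array median on every array. Since fewer than 5 rose, the next by unadjusted p are given as values: Abca8a (1.08 ± 0.18, adjusted p = 0.0501), Prnp (0.65 ± 0.11, adjusted p = 0.0626) and Nrn1 (0.49 ± 0.09, adjusted p = 0.0626).

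In wild type, 7 lists passed with the preset correlation and 0 with an estimated correlation. The PPAR alpha list (27 measured, 0 called, 5 lower when adjusted over the list alone) had 24 negative members, a median of -0.157 and an adjusted p of 1.29e-06, but adjusted p = 0.227 with an estimated correlation. The lipid droplet list (22 measured, 0 called, 3 lower when adjusted over the list alone) had a median of -0.269 and an adjusted p of 0.000740, but adjusted p = 0.414 with an estimated correlation. In it, Plin2, a droplet coat protein, was at -0.60 ± 0.16 (adjusted p = 0.310). The acute phase list (22 measured, 0 called, 0 when adjusted over the list alone) had 20 negative members and an adjusted p of 8.55e-05, but adjusted p = 0.567 with an estimated correlation. The interferon list (19 measured, 0 called, 4 higher when adjusted over the list alone) had a median of 0.415 and an adjusted p of 6.60e-05, but adjusted p = 0.284 with an estimated correlation. In it, Gbp3 was at 1.21 ± 0.24 (adjusted p = 0.0779). Bile acid genes (20 measured, 0 called, 2 higher and 2 lower when adjusted over the list alone, median 0.183) and xenobiotic genes (20 measured, 2 lower, and 1 higher and 4 lower when adjusted over the list alone, median -0.143) both had an adjusted p of 0.00536, but adjusted p = 0.227 and adjusted p = 0.479 with an estimated correlation. Lipoprotein genes (20 measured, 1 lower, and 1 higher and 2 lower when adjusted over the list alone, median -0.150) had an adjusted p of 0.0226, but adjusted p = 0.414 with an estimated correlation. The fatty acid synthesis list, which holds Scd1, did not pass (adjusted p = 0.461).

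The count was 0 without the intensity trend and 0 without the 4 arrays with pancreatic transcripts, which leaves 1 WT high-fat array, 5 without the filter on low signal, 4 with both tissue scores as covariates, and 21 with array quality weights. Leaving out single arrays gave 2 (WT high-fat replicate 1), 3 (WT high-fat replicate 2), 5 (WT normal replicate 1), 5 (WT normal replicate 2), 4 (WT normal replicate 3) and 20 (αERKO normal replicate 1).

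In the knockout high-fat diet raised several female-biased genes. Cyp2b9, a female-biased cytochrome P450, rose by 1.69 ± 0.17 (3.23-fold, adjusted p = 0.000483), from a log2 signal of 11.73 ± 0.34 to 13.43 ± 0.27 (SD, n = 3). Slc22a27 rose by 1.91 ± 0.22 (adjusted p = 0.00120), Hao2 by 2.04 ± 0.30 (adjusted p = 0.00819) and Cyp2b13 by 2.12 ± 0.29 (adjusted p = 0.00484). Ces2a fell by 1.22 ± 0.12 (adjusted p = 0.000483), Pltp by 1.09 ± 0.18 and Igfbp2 by 1.17 ± 0.17. In all, 59 genes were called, 41 up and 18 down, 26 of them at least 2-fold. For 2 of the 20 called genes named here, Cyp2b13 and Ttc39a, the lower group lay below the array median on every array, so the sizes of these rises are imprecise.

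Of 23 measured female-biased genes, 5 rose and 0 fell (7 rose when adjusted over the list alone), with a median of 0.176 and an adjusted p of 4.79e-05, or adjusted p = 0.0373 with an estimated correlation. Without the 4 arrays with pancreatic transcripts the list had an adjusted p = 0.272 with an estimated correlation, and with all arrays its 13 members outside near-identical gene families had an unadjusted p of 0.0334, or 0.0544 with an estimated correlation. The fifth called gene was Cyp17a1, a steroid hydroxylase and lyase (1.16 ± 0.22, adjusted p = 0.0371), which is named here after its value was seen. The 17 male-biased genes had 0 called members and 0 when adjusted over the list alone, a median of -0.309 and an adjusted p of 0.00786, but adjusted p = 0.495 with an estimated correlation. Other rises were Ttc39a (2.32 ± 0.41), the water channel Aqp8 (1.61 ± 0.25), the transporter Slc22a29 (1.56 ± 0.16), an uncharacterised clone, the pyruvate kinase Pklr (1.15 ± 0.20), the clock repressor Cry1 (1.07 ± 0.22) and the acyltransferase Agpat2 (0.59 ± 0.12). Falls were Cyp4a31 (-1.36 ± 0.21), Cadm4 (-1.26 ± 0.25), the cationic amino acid transporter Slc7a2 (-1.08 ± 0.15), Cyp2c23 (-1.02 ± 0.15), Ehhadh (-0.79 ± 0.09) and Ggt5 (-1.46 ± 0.25), for which 1 of 3 probe sets went the other way.

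Cholesterol synthesis genes had the smallest list p in this comparison with the preset correlation, with 17 of 20 members positive, a median of 0.572 and an adjusted p of 9.15e-06, but adjusted p = 0.607 with an estimated correlation. In it, 0 genes were called over all genes, and 7 rose and 1 fell when adjusted over the list alone. Hmgcs1, the synthase upstream of mevalonate, was at 1.09 (adjusted p = 0.141). Much of this came from αERKO high-fat replicate 3, without which the list median was 0.285 (adjusted p = 0.0173) and Hmgcs1 was at 0.71 (adjusted p = 0.220). The PPAR alpha list (27 measured, 1 lower, 1 lower when adjusted over the list alone, median -0.105) had an adjusted p of 0.00194, but adjusted p = 0.495 with an estimated correlation. The hormone signalling list (20 measured, 1 lower, 1 lower when adjusted over the list alone, median -0.305) had an adjusted p of 0.00334, but adjusted p = 0.322 with an estimated correlation. The stellate cell and fibrosis list (15 measured, 0 called, 3 higher when adjusted over the list alone, median 0.321) had an adjusted p of 0.0166, but adjusted p = 0.695 with an estimated correlation.

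**Figure D3:**
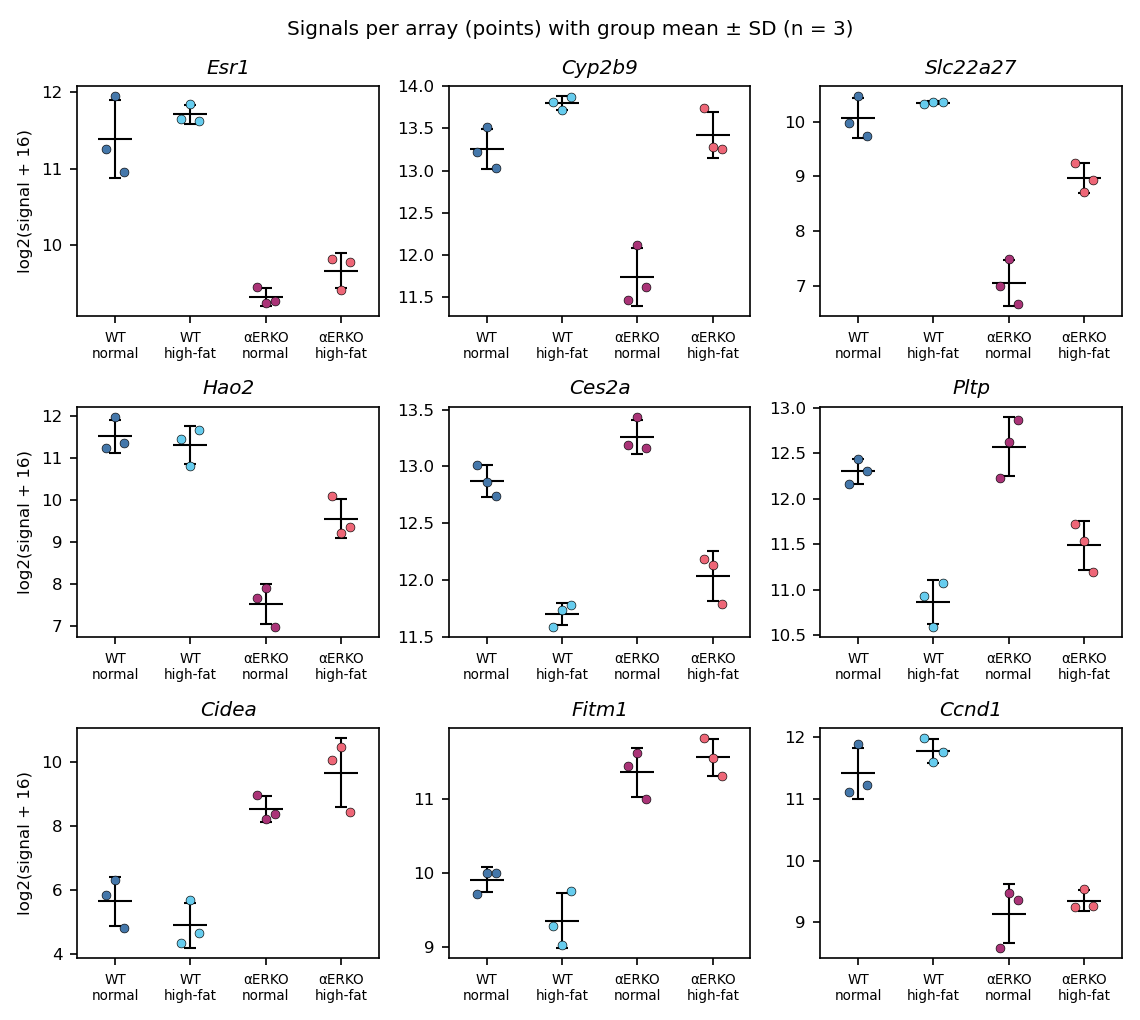
Log2(signal + 16) of 9 genes on each array (points) with the group mean ± SD (bars, n = 3) for WT and αERKO on normal and high-fat diet. Esr1 and Ccnd1 were lower in the knockout on both diets, Cyp2b9, Slc22a27 and Hao2 rose with high-fat diet in the knockout, Ces2a and Pltp fell with high-fat diet in both genotypes, and Cidea and Fitm1 were higher in the knockout on both diets.

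The count fell to 30 without WT high-fat replicate 2, 23 without αERKO high-fat replicate 1, 13 without αERKO high-fat replicate 2, 22 without αERKO normal replicate 1, 32 without αERKO normal replicate 2 and 15 without αERKO normal replicate 3. It was 12 without the intensity trend, 22 with only the groups compared in the fit, 26 with the mean of all probe sets, 33 and 26 with the pancreatic score alone and with both tissue scores as covariates, 18 without the 4 arrays with pancreatic transcripts and 187 with array quality weights.

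The diet responses of the 2 genotypes shared 4 called genes, Gamt (0.90 in wild type and 0.85 in the knockout) and Tlcd2 (0.82 and 0.99), which rose, and Ces2a and Pltp, which fell. Independent lists would share 0.00669 rising and 0.0103 falling genes. Of the 64 genes called in either genotype, 53 had the same sign in both. Across all 12264 genes the Pearson correlation of the log2 differences was 0.11 and the Spearman correlation 0.15. The 2 comparisons share no arrays, but they too share the variance estimate of each gene, so the numbers for independent lists are only a rough guide.

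No gene's diet response differed between the genotypes past the threshold. In the interaction test of limma 0 genes were called, with a smallest adjusted p of 0.177, and 728 genes had an unadjusted p under 0.05 against 613 by chance. The 5 genes with the smallest unadjusted p and a more positive diet difference in the knockout were Wfdc2 (1.13 ± 0.18), Nat8f5 (1.57 ± 0.26), Hao2 (2.25 ± 0.42), Slc22a27 (1.62 ± 0.32) and Paqr9 (1.15 ± 0.23). Those with a more negative one were Igfbp2 (-1.38 ± 0.24), the complement component C8b (-1.14 ± 0.21), Pnn (-1.03 ± 0.19), Slc7a2 (-1.03 ± 0.21) and Cyp4a31 (-1.48 ± 0.30). So the genes called in the knockout and not in wild type are not shown to respond differently. Igfbp2 was called in the interaction with the pancreatic score as a covariate (-1.57, adjusted p = 0.00829), and Cyp2b13 (2.09, adjusted p = 0.00146) and Leap2 (1.31, adjusted p = 0.0446) were called without αERKO high-fat replicate 3. In the interaction 7 lists passed with the preset correlation and 0 with an estimated correlation.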

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

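The counts over other splits of the arrays and the first test of the sex-biased gap, that on normal diet with all arrays and all members, were fixed before their results were seen, and every other test in this part was chosen after the result was seen, as were the 3 alternatives that deal with pancreatic and muscle transcripts. For the higher female-biased genes in the knockout on high-fat diet, the requirement that the members outside gene families pass with both correlations was made after the preset p had been seen, which alone would have counted against the families. The test of pancreatic tissue by the mean of the members on each array replaced one by list p-values, which had left that explanation open, after those p-values had been seen.

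The diet response of 7 gene lists differed between genotypes in the interaction test with a preset correlation, as the knockout's diet difference minus that of wild type. The median was 0.39 for cholesterol synthesis (adjusted p = 0.00279, and adjusted p = 0.649 with an estimated correlation), which fell to 0.149 (adjusted p = 0.354) without αERKO high-fat replicate 3, and 0.382 for lipid droplets (0.000868, and adjusted p = 0.543 with an estimated correlation). It was 0.329 for acute phase genes (0.000296, and adjusted p = 0.649 with an estimated correlation) and 0.276 for female-biased genes (0.00444, and adjusted p = 0.214 with an estimated correlation). It was -0.196 for male-biased genes (0.0316, and adjusted p = 0.543 with an estimated correlation) and -0.209 for hormone signalling genes (0.0345, and adjusted p = 0.543 with an estimated correlation). It was -2.862 for the pancreatic acinar genes (0.0350, and adjusted p = 0.649 with an estimated correlation), whose scores were high on 2 of 3 WT high-fat arrays.

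Probe sets with several gene symbols or none, 3806 of which passed the filter, were tested apart from the gene table with limma. Of these, 1 was called for diet in wild type, 5 for diet in the knockout, 22 for genotype on normal diet and 17 for genotype on high-fat diet.

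Other splits of the same arrays were counted for each result. A split of 6 arrays into 3 and 3 has 10 forms, so the share cannot go below 0.1. The real split gave 9 genes for diet in wild type (highest other split 0), 59 for diet in the knockout (1), 150 for genotype on normal diet (1) and 243 for genotype on high-fat diet (0), and in each case 1 of the 10 splits reached the real count. The number of gene lists past the threshold with the preset correlation behaved differently. For diet in wild type 3 of 10 splits gave as many as the real 7 (highest other 10), for diet in the knockout 8 of 10 gave as many as the real 6 (highest other 10), for genotype on normal diet 7 of 10 gave as many as the real 6 (highest other 10), and for genotype on high-fat diet 1 of 10 reached the real 12 (highest other 8). For the interaction 60 splits were used, the real split and others drawn at random, with diet labels reassigned within each genotype. Of these, 17 of 60 gave as many lists as the real 7 (highest other 10), so chance cannot be excluded for that count of lists. The real count of genes was 0, which all 60 of 60 splits reach by necessity, so their number decides nothing. The highest other split called 13 genes, and the cause was not examined. Such splits can exchange the diet labels of the knockout and not those of wild type. A diet effect common to both genotypes can then enter the interaction, so these splits are no clean reference for it. Since other splits of the single comparisons often passed as many lists, list calls with the preset correlation alone carry little weight in these data. For the overlaps 1 of 100 pairs of splits reached the real 4 genes for diet and 1 of 100 the real 82 for genotype, with 0 in the highest other pair in both. No other pair called enough genes to share more than 1, so these splits add nothing to those of the single comparisons.

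Male-biased genes were higher and female-biased genes lower in the knockout, and the gap between the list medians on normal diet was 2.25, against a 95th percentile of 0.17 for 10000 random pairs of lists matched on signal. Random pairs do not move together as related genes can, so their percentiles are a lenient bound. Without the 4 arrays with pancreatic transcripts the gap was 2.53 (0.18 for random pairs), and among the 9 male-biased and 13 female-biased members outside the broadly defined families with near-identical genes it was 1.64 (0.22), which argues against pancreatic tissue and against shared probes as the whole cause. The hypothesis that the knockout female liver may shift towards the male pattern remains, and the gap on high-fat diet was 2.15 (0.18). Whether such a shift would come from loss of the receptor in liver or from altered hormones in a mouse lacking it in all tissues was not tested and stays open.

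Pancreatic acinar transcripts were high on 4 of 12 arrays, in 3 groups. Pancreatic tissue taken along at dissection may be the source, since the 7 genes exceeded their level on the other 8 arrays in nearly the same ratio on each array. The largest SD of the log2 ratio over the genes was 0.28 (bound 0.5), with 78.8%, 41.3% and 6.4% of the excess of WT normal replicate 2 in αERKO normal replicate 1, WT high-fat replicate 3 and WT high-fat replicate 2. Prss2 had signals of 24900, 17500, 8440 and 1350 on the 4 arrays and Cela1 23800, 22000, 12900 and 2550. For a response of the liver to diet or genotype, the arrays of a group should be alike. Their scores differed by at least 6.32 on the log2 scale in each affected group (bound 2), so group membership alone does not give the scores. That spread is how the pattern was noticed, so passing the bound was fixed in advance and is no test. The scores of 13 pancreatic genes outside the list differed by at least 4.68. Those genes were chosen after the arrays were seen and are no independent support.

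With high-fat diet in the knockout 5 of 23 female-biased genes rose, with a list median of 0.176, and the gap between the male-biased and female-biased medians moved by -0.49, against a 5th percentile of -0.15 for random pairs of lists, as a partial return of sex-biased genes towards the wild type female pattern would give. The larger part was the male-biased median of -0.309, with 0 called members. Random pairs do not move together as related genes can, and another split of the knockout arrays reached a gap of 0.44 in size. Passing that bound therefore carries little weight. The mean log2 difference of the 23 members was 0.451 ± 0.07 (SE between arrays) with all arrays. It lies above the list median because the 5 called genes, picked from the same data, weigh on it. So the mean does not show a rise across the list. For those genes mainly, pancreatic tissue is argued against as the whole cause, since the mean was 0.425 ± 0.10 without the 4 arrays, with a lower 95% bound of 0.148. The list call with an estimated correlation ended there (adjusted p = 0.272, and 8.27e-05 with the preset correlation) with a similar difference and a larger error from fewer arrays, and Cyp2b13 went from 2.12 to 2.11 and Cyp2b9 from 1.69 to 1.56. Near-identical gene families cannot be told apart from a wider rise, because the 13 members outside the families had a median of 0.17 against 0.53 for the 10 inside, and an unadjusted camera p of 0.0334 with the preset and 0.0544 with an estimated correlation. In the 10 splits of the 6 knockout arrays 1 split reached the real size of 0.49 (highest other 0.44), the share cannot go below 0.1, and the αERKO normal arrays enter both this difference and the genotype difference on normal diet, so that the return stays a hypothesis.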

How the results depend on the processing

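The alternatives with pancreatic or muscle scores and without the 4 arrays with pancreatic transcripts were chosen after seeing the data, and all others were planned. Without the 4 arrays a single WT high-fat array remains, which is assumed to vary like the other groups. Signals near the array median limit the lowest values, and the lists of changed genes are uncertain in extent. Of 95 called results for named genes, 57 kept their call when any single array was left out, and 52 without the intensity trend. Under any alternative 0 of the 95 reversed. In all of them every array of a group lay above every array of the other, which the rule for the largest changes required. Leaving out arrays therefore could not turn their direction. The 0 reversals say little about direction in the full lists of changed genes. The cause of the changes below was not tested, apart from the smaller number of samples where arrays were left out.

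Genes called for diet in wild type numbered 9. The count was 5 without the filter, 0 without the trend, 21 with array quality weights, 4 with both tissue scores as covariates, 0 without the 4 arrays, and 2 to 20 with single arrays left out. For diet in the knockout (59) it was 26 with the mean of all probe sets, 12 without the trend, 22 with only the groups compared, 187 with array quality weights, 33 with the pancreatic score, 26 with both scores, 18 without the 4 arrays, and 13 to 81 with single arrays left out. For genotype on normal diet (150) it was 83 without the trend, 71 with only the groups compared, 95 with both scores, 80 without the 4 arrays, and 85 to 142 with single arrays left out. For genotype on high-fat diet (243) it was 116 without the trend, 944 with array quality weights, 108 with both scores, 60 without the 4 arrays, and 108 to 308 with single arrays left out. The interaction (0) gave 1 gene with the pancreatic score as a covariate, 1 with both scores as covariates, and 0 to 2 with single arrays left out.

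Genes shared by both diet comparisons (4) numbered 2 with the mean of all probe sets, 0 without the trend, 2 with only the groups compared, 12 with array quality weights, 2 with both scores as covariates, 0 without the 4 arrays, and 1 to 4 with single arrays left out. Genes shared by both genotype comparisons (82) numbered 47 without the trend, 52 with only the groups compared, 46 with both scores and 30 without the 4 arrays. The 38 lists past the threshold became 6 with an estimated correlation. Of the 38, 19 passed whichever single array was left out. Without the 4 arrays 28 passed, 8 did not, and 2 turned in test direction without passing in the new one. Esr1 kept its direction and call under every alternative, from -2.29 to -1.79 on normal diet and from -2.12 to -1.92 on high-fat diet with single arrays left out.

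Some lists turned in test direction, in part with a median that kept its sign, and no turned list passed in its new direction. The median of the pancreatic list for genotype on high-fat diet went from -3.953 to -0.189 with the pancreatic score and -0.027 with both scores, still negative. In the interaction it went from -2.862 to 0.274 with the pancreatic score and 0.269 with both scores, a change of sign, and to -0.056 without the 4 arrays, still negative. The hormone signalling list in the interaction went from -0.209 to 0.004 without the 4 arrays.

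With the replicate number as a block the counts were 6, 51, 131, 210 and 0 genes, 3 and 74 shared genes and 38 lists, each within 1.5 times the unblocked count. The genes themselves changed more: 4 of 9 kept their call for diet in wild type and 45 of 59 for diet in the knockout. For genotype 119 of 150 kept it on normal diet and 191 of 243 on high-fat diet. Pairing by number was not detected. Deviations of same-numbered arrays correlated between -0.30 and 0.21, 4 of 18 pairs exceeded 0.1, and 5 of 12 arrays correlated best with their own number. The labels do not say what the numbers mark, and with 3 arrays per group these values cannot exclude a shared day or batch.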

Other observations

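Further genes called for genotype, on both diets unless noted, were chosen here after their values were seen. The complement genes C8a (1.78 ± 0.28 on normal and 1.37 ± 0.28 on high-fat diet) and C9 (1.20 ± 0.14 and 0.84 ± 0.14), whose products form the membrane attack complex, were higher in the knockout. C8b (1.73 ± 0.15) and C6 (1.86 ± 0.24), which is on the male-biased list, were higher on normal diet and missed the threshold on high-fat diet (adjusted p = 0.0546 and 0.0564). The efflux transporter Abcg2 (0.93 ± 0.11 and 1.24 ± 0.11), Alas2, an enzyme of heme synthesis on the list of red blood cell markers (1.86 ± 0.22 and 1.89 ± 0.22), and the NADPH oxidase Nox4 (2.15 ± 0.19 and 1.07 ± 0.19) were higher as well. Lower genes included Hamp2, related to the iron hormone hepcidin (-1.82 ± 0.20 and -1.14 ± 0.20), Inhba, an activin subunit (-1.49 ± 0.21 and -1.25 ± 0.21), Cyp39a1, an oxysterol hydroxylase (-1.29 ± 0.15 and -1.54 ± 0.15), and Apom, an apolipoprotein (-0.74 ± 0.15 and -0.94 ± 0.15). No test of these as groups was run.

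There were 9 lists that passed in no comparison, and the smallest adjusted p of each over the 5 contrasts is given here with the list's median log2 difference. It was 0.0671 for fatty acid synthesis (median 0.166, interaction), 0.0748 for periportal markers (-0.162, diet in wild type), 0.0883 for glucose genes (0.122, diet in wild type), 0.124 for sinusoidal endothelial markers (-0.208, genotype on high-fat diet) and 0.281 for the cell cycle (-0.120, genotype on normal diet). It was 0.297 for lymphocyte markers (-0.406, genotype on high-fat diet), 0.411 for the circadian clock (-0.157, interaction), 0.411 for neutrophil markers (-0.351, interaction) and 0.469 for pericentral markers (0.130, diet in the knockout).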
